A study of Mus musculus with 18 samples.

How the data were processed

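Bulk RNA-seq was run on total RNA of mouse embryonic stem cells (ESCs) of a parental line and of a line labelled Oct1 cKO, at days 0, 2 and 6 of differentiation with retinoic acid. The values used are the deposited counts: whole numbers of reads per Ensembl gene for 18 libraries, with no normalization, in 1 table of 21995 genes. Per the labels' protocols, cells were harvested with trypsin, RNA was isolated with Trysol and libraries followed the standard Illumina protocols. Per the submitters' processing notes, the processing involved Novoalign, the genome builds mm10 and GRCm38, and DESeq2 1.10.0, with no role or order given. The read counter, the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Multigene families such as Zscan4, Tcstv and Usp17 and the near-identical histone genes can share reads, so the level of a single such gene is uncertain. Histone genes of the replication-dependent kind also lack the usual poly(A) tail, so their level depends on how RNA was selected, which the labels do not say beyond total RNA. Overlapping and antisense genes cannot be told apart without strand.

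Each library was placed in 1 of 6 groups of 3 by its genotype and differentiation day in the labels, and each column of the table was matched to a library by its title. Replicate numbers follow the order of the samples and pair nothing across groups. The labels do not say that the 3 libraries of a group came from separate cultures, so every p-value measures the spread between these libraries, which may be technical. Replicates were compared by a chi-square statistic of their counts over genes. No pair fell within sampling noise, so all 18 libraries were kept.

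Total counts ran from 13694126 to 19296966 per library. A gene at 0 counts in a library is compatible with up to 3 counts at this depth, and folds against a group at 0 are given as lower bounds against that floor of 3 counts per library. Such bounds cover counting error only. In the comparisons no fold is printed where a group held 1 to 3 counts over its libraries, and only CPM (counts scaled to library size) are given there.

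The main test was the quasi-likelihood test of edgeR 4.0.16 (estimateDisp, glmQLFit with robust settings, glmQLFTest) in R 4.3.3, with TMM scaling factors. Genes passed edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 18352 genes. All 18 libraries entered 1 fit with a coefficient per group. Contrasts gave 9 comparisons: Oct1 cKO against parental at each day, day 2 and day 6 against day 0 within each genotype, and the genotype by day interaction for day 2 and for day 6. Adjusted p is the Benjamini-Hochberg value within a comparison, and genes under 0.05 were called. Log2 fold changes are given with a standard error (SE) derived from the quasi-likelihood F statistic, and group levels as mean CPM with the standard deviation (SD) over 3 libraries.

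Gene lists were written from textbook knowledge, not from these libraries. The 25 lists were general and naive pluripotency, formative and primed pluripotency, primitive streak and early mesoderm, muscle and heart muscle, endothelium and blood, neural progenitor, neuron, neural crest, definitive endoderm, extraembryonic endoderm, trophoblast, retinoic acid response, Hox genes of paralogue groups 1 to 5, Hox genes of paralogue groups 6 to 13, targets of TGF-beta, nodal and BMP signalling, fibroblast (for feeder cells), epithelial to mesenchymal, proliferation, p53 target and cell death, glycolysis, 2-cell-like, imprinted, X inactivation and Y chromosome, replication-dependent histone H2B, and other replication-dependent histones. Each was tested with camera from limma 3.58.1, which compares the test statistics of the list with those of the other genes. Camera used log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Its p-values are 2-sided and adjusted over all 225 tests of 25 lists in 9 comparisons. Camera with an estimated correlation and fry, which tests the list alone, were alternatives.

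Named genes followed a rule. It takes Pou2f1, the 8 called genes with the largest increase and the 8 with the largest decrease (5 and 5 for the interactions) among genes with a mean log2 CPM of at least 1, groups that do not overlap and an official symbol, up to 4 members of each list with the smallest adjusted p, and a fixed set of genes named in every comparison, of which 23 are given. Some genes that the rule names are not reported here. The grouping, the tests, the lists, this rule and the first set of alternatives below were fixed before the data were examined.

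Alternatives fixed then were the DESeq2 size factors in the same edgeR fit, library sizes with no scaling factor, no filter on low counts, DESeq2 1.42.0, a fit of only the libraries compared, a fold minimum of 2, and leaving out each library in turn. Testing against a fold of 1.5 with glmTreat and leaving out the genes of chromosome 11 were chosen after seeing the data. Chromosomes, coordinates, GC content and lengths came from GENCODE annotation of GRCm38, matched by Ensembl identifier. No column of the table was left out.

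The chain was tested on simulated counts for the comparison of genotypes at day 0, drawn from the real means and library sizes for 18071 tested genes with 200 genes changed. It called 57 of 67 genes changed 1.5-fold (85.1%), 63 of 67 changed 2-fold (94%) and 65 of 66 changed 4-fold (98.5%). Of 17871 unchanged genes, 12 were called, which is 6.1% of the calls. The simulated counts followed the negative binomial model that the test itself fits. The real comparison at day 0 called 53.5% of genes, so these rates do not show how scaling and error control hold when that many change. A simulated offset of -0.4 for chromosome 11 was recovered as -0.41. Python 3.11.15 with matplotlib 3.10.9 drew the figures.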

Results

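Gene expression was measured by RNA-seq in mouse ESCs, pluripotent cells that can be grown in culture and can form every lineage of the embryo. Parental cells were compared with cells labelled Oct1 cKO, which the source labels also call KO. Oct1 is the product of Pou2f1, a transcription factor of the POU family that binds the octamer DNA motif. Cells were taken undifferentiated at day 0 and after 2 and 6 days in medium with 1.5 ug/ml retinoic acid on 0.01% gelatin. Retinoic acid is a derivative of vitamin A that activates nuclear receptors and drives ESCs out of pluripotency. The series title names mesodermal lineage specification and Smad factors, the nuclear mediators of TGF-beta, nodal and BMP signals, so genes of those groups are reported at every day. Each of the 6 groups held 3 libraries, with 13694126 to 19296966 counts per library.

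Day separated the libraries more than genotype. The first principal component of log2 CPM held 74.77% of the variance over the 500 most variable genes (CPM are counts scaled to library size), the second 16.77% and the third 5.87%. Correlations between libraries of a group ran from 0.991 to 0.9953 across genes, which are not independent replicates. The closest pair of libraries from different groups had a correlation of 0.9754, at day 0. Among the Oct1 cKO libraries at day 0, replicate 3 stood apart. Its chi-square statistic per degree of freedom was 12.002 and 11.59 against replicates 1 and 2, and those differed by 1.235, which is above sampling noise (SD 0.012). Its share of ribosomal protein gene counts was 6.686%, against 5.417% and 5.48%. Mitochondrial genes took 2.095 to 2.185% of counts in the parental libraries at day 0 and 1.292 to 1.437% in the Oct1 cKO libraries.

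**Figure D1:**
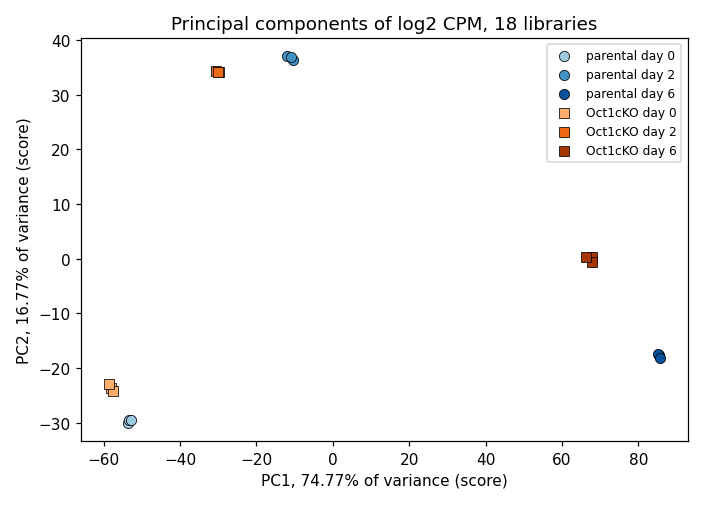
Principal components 1 and 2 of log2 CPM for the 18 libraries, with 1 point per library, a colour for each of the 6 groups and marker shape for genotype. The axes hold 74.77% and 16.77% of the variance, and the 3 libraries of each group lie together.

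Pou2f1 (ENSMUSG00000026565, GRCm38 chromosome 1, 165865154 to 166002678, minus strand) was lower in the Oct1 cKO at every day, and its counts were not lost. At day 0 the parental libraries held 135, 124 and 127 CPM and the cKO libraries 87.2, 88.2 and 62.4. At day 2 they held 105, 97.9 and 106 against 59.5, 60.8 and 58.8, and at day 6 they held 64.9, 61.1 and 64.2 against 36, 45.3 and 44.5. The log2 fold change was -0.70 ± 0.10 (SE) at day 0 (adjusted p = 1.36e-05), -0.78 ± 0.10 at day 2 (adjusted p = 2.81e-06) and -0.60 ± 0.11 at day 6 (adjusted p = 8.6e-05), with each cKO library of a day below each parental one. Counts per gene cover the whole of Pou2f1, and the labels do not say which part was deleted, so reads from undeleted exons are included. Pou2f1 was also lower at day 6 than at day 0 in the parental cells, by -1.02 ± 0.10 (adjusted p = 3.91e-08), and in the cKO cells, by -0.91 ± 0.11 (adjusted p = 6.13e-07). At day 2 it was lower than at day 0 by -0.32 ± 0.10 in parental cells (adjusted p = 0.00538) and by -0.40 ± 0.11 in cKO cells (adjusted p = 0.00235). With library sizes alone these day 2 calls were lost, with adjusted p = 0.884 (4.21e-11 to 0.884 over the alternatives) and adjusted p = 0.0635 (3.08e-12 to 0.0635). Its change from day 0 was not called different between genotypes at day 2 (-0.08 ± 0.14, adjusted p = 0.66) or at day 6 (0.11 ± 0.15, adjusted p = 0.548). Without replicate 3 of the cKO at day 0 the day 2 difference passed, at -0.24 (adjusted p = 0.00533, with 0.00533 to 1 over the alternatives).

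**Figure D2:**
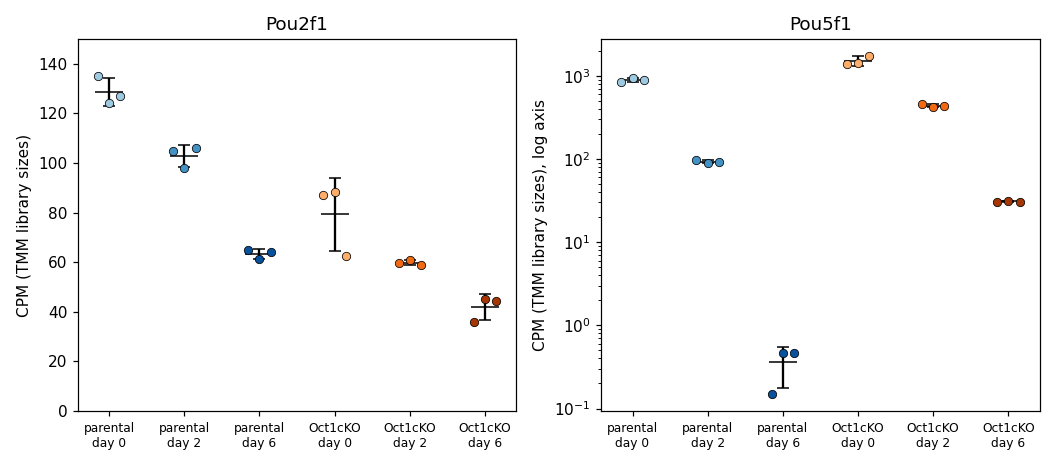
CPM of Pou2f1 (linear axis) and Pou5f1 (log axis) by genotype and day, with a point per library and a bar for the mean ± SD of 3 libraries. Pou2f1 averaged 129 CPM in parental and 79.3 in Oct1 cKO cells at day 0, and Pou5f1 averaged 0.362 and 31 CPM at day 6.

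The genes of chromosome 11 were lower as a set in the Oct1 cKO. Over its 946 genes at 5 CPM or more, the median log2 fold change between genotypes was -0.38 at day 0, -0.38 at day 2 and -0.39 at day 6. Each of the 9 Oct1 cKO libraries had a median between -0.41 and -0.35 on this chromosome. The other autosomes had medians from -0.06 to 0.13, from 0.04 to 0.16 and from 0.03 to 0.17 at those days. On chromosome 11, 69.8%, 68.6% and 64.8% of genes were called lower, against 23.4 to 36.3%, 26.9 to 34.1% and 32.8 to 41% on the others. Named genes on this chromosome include Hand1, Meox1, Lhx1, Myl4, Myl7, Pecam1, Sox9, Ngfr, Meis1, Hoxb1 to Hoxb9, Col1a1, Cldn7, Top2a and Irgm1, and the lists hold 38 such members. The median describes the set, and single genes of the chromosome moved either way.

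**Figure D3:**
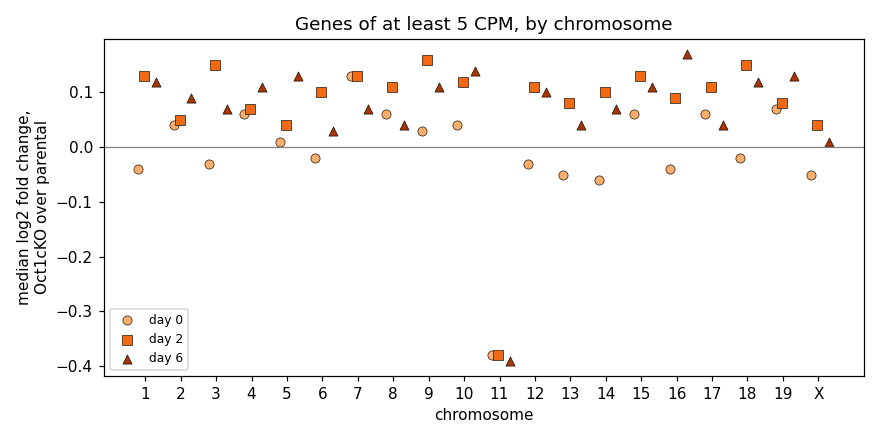
Median log2 fold change between Oct1 cKO and parental cells for each chromosome at days 0, 2 and 6, over genes at 5 CPM or more. Chromosome 11 lies at -0.38, -0.38 and -0.39, and the other autosomes between -0.06 and 0.17.

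The first comparison asks what differed between the genotypes before retinoic acid. Pou5f1, which encodes Oct4, a POU factor at the core of the pluripotency network, rose from 893 ± 39.6 CPM (SD, n = 3) in parental to 1520 ± 193 in Oct1 cKO cells (log2 fold change 0.76 ± 0.06, adjusted p = 5.72e-11). Lefty1, an inhibitor and target of nodal signalling, fell from 107 ± 7.18 to 21.1 ± 2.26 CPM (-2.33 ± 0.07, adjusted p = 4.13e-26). Col1a1, a fibrillar collagen chain on chromosome 11, fell from 540 ± 19.5 to 155 ± 3.24 CPM (-1.80 ± 0.08, adjusted p = 5.52e-14). Genes of 2-cell-like cells, a rare state of ESC cultures that resembles the 2-cell embryo, rose together. Nanog (0.11 ± 0.05, adjusted p = 0.0729), Sox2 (-0.04 ± 0.05, adjusted p = 0.507) and Zfp42 (0.07 ± 0.05, adjusted p = 0.279) were not called.

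In all, 9816 of 18352 genes were called at day 0, 4854 higher and 4962 lower in the Oct1 cKO, and 2333 of them differed at least 2-fold. Of the 23 genes named in every comparison, 6 were higher: Pou5f1, Eomes, Sox1, Tubb3, Cdx2 and Rarb. Another 4 were lower: Pax6, Foxa2, Lefty1 and Col1a1. The other 13 were not called: Nanog, Sox2, Zfp42, Fgf5, Mixl1, Hand1, Kdr, Gata4, Gata6, Cyp26a1, Hoxb1, Id1 and Cdkn1a. Among the called genes, the libraries of both groups overlapped for Foxa2 alone. Eomes, a T-box factor of the primitive streak, rose from 5.4 to 14.4 CPM (1.42 ± 0.11, adjusted p = 2.85e-13), and Sox1, an early neural factor, from 0.894 to 3.93 CPM (2.15 ± 0.25, adjusted p = 5.41e-09). Pou2f3, another POU gene, rose from 8.56 ± 0.914 to 89.4 ± 2.27 CPM (3.38 ± 0.08, adjusted p = 2.88e-28). Other large increases were in Zfp352 (3.71 ± 0.16), Kcnd3 (3.35 ± 0.22), Tcstv3 (3.25 ± 0.17), Ccser1, Foxd1, Ano1 and Vax2. The largest decreases were in Crlf2 (-4.52 ± 0.19), Tcrg-C1 (-3.84 ± 0.21), Usp26 (150 to 14.4 CPM, -3.39 ± 0.08), Aass, Igfbp4 (66.8 to 7.32 CPM, -3.19 ± 0.08), Osbpl6, Fam183b and Otog.

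Of 14 tested genes of the 2-cell-like list, 13 were higher and 0 lower, and 14 were higher when adjusted over the list alone (camera adjusted p = 6.88e-08). Zscan4d rose from 6.29 to 32.1 CPM (2.35 ± 0.11) and Tcstv3 from 1.12 to 10.8 CPM, within families whose members can share reads. Fibroblast genes had 15 of 18 lower and 0 higher (camera adjusted p = 5.4e-06, adjusted p = 0.066 with an estimated correlation), among them Col1a2 (207 to 59.1 CPM, -1.81 ± 0.07), Fbln2 (299 to 97.2 CPM, -1.62 ± 0.05) and Postn (41 to 13.7 CPM, -1.59 ± 0.09). In the general and naive pluripotency list, 14 of 26 genes were higher and 4 lower (camera adjusted p = 0.0163, adjusted p = 0.0939 with an estimated correlation). Prdm14 rose from 27.5 to 67.6 CPM (1.30 ± 0.08) and Utf1 from 53.5 to 126 CPM (1.24 ± 0.07), and Dppa3 fell from 77.7 to 15.5 CPM (-2.31 ± 0.09). Glycolysis genes had 11 of 17 lower and 3 higher, or 4 higher when adjusted over the list alone (camera adjusted p = 0.00465, adjusted p = 0.442 with an estimated correlation). Ldhb fell from 315 to 99.6 CPM (-1.66 ± 0.06) and Pfkp from 869 to 362 CPM (-1.26 ± 0.05). Of 32 other replication-dependent histones, 8 were lower and 0 higher, or 6 lower when adjusted over the list alone (camera adjusted p = 0.0205, adjusted p = 0.255 with an estimated correlation). That call was lost without replicate 2 of the parental cells (adjusted p = 0.0747, with 0.00483 to 0.0747 over the alternatives).

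In the primitive streak and early mesoderm list, 10 of 28 genes were higher and 2 lower at day 0, and the list was not called (camera adjusted p = 0.0989). A fit of only the libraries compared called it (adjusted p = 0.0158, with 0.0158 to 0.178 over the alternatives). Bmp4 rose from 1.64 to 6.04 CPM (1.89 ± 0.18, adjusted p = 3.96e-11) and Tcf15 from 1.97 to 5.96 CPM (1.60 ± 0.19, adjusted p = 4.14e-09). Of 23 targets of TGF-beta, nodal and BMP signalling, 8 were higher and 12 lower, with no call for the list (camera adjusted p = 0.193). Skil fell from 153 to 79.5 CPM (-0.95 ± 0.06) and Smurf2, on chromosome 11, from 85.2 to 50 CPM (-0.77 ± 0.06). Nanog was called higher under DESeq2, with its size factors in edgeR, with no filter and without replicate 3 of the cKO, with adjusted p from 0.0107 to 0.185 over the alternatives. The call of Foxa2 (0.181 and 0.0251 CPM) was lost under DESeq2 and when any of 3 single libraries was left out, with adjusted p from 0.0133 to 0.175.

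The second comparison asks what differed after 2 days of retinoic acid. Meox1 and Kdr were among the largest decreases in the Oct1 cKO, while the early mesoderm list was not called (camera adjusted p = 0.16). Meox1, a somite homeobox gene on chromosome 11, fell from 19.6 ± 1.37 to 0.477 ± 0.125 CPM (-5.33 ± 0.22, adjusted p = 3.39e-21), and Kdr, the VEGF receptor of early mesoderm and endothelium, fell from 10.2 ± 0.907 to 0.723 ± 0.183 CPM (-3.80 ± 0.17, adjusted p = 7.47e-21). Hoxb1, a direct retinoic acid target on chromosome 11, fell from 346 ± 5.53 to 88.7 ± 2.34 CPM (-1.96 ± 0.05, adjusted p = 5.86e-27). Pluripotency genes were higher: Pou5f1 rose from 93.2 ± 4.6 to 439 ± 17.9 CPM (2.23 ± 0.07, adjusted p = 7.11e-21) and Fgf4 from 5.63 ± 0.517 to 50.1 ± 2.18 CPM (3.15 ± 0.09, adjusted p = 1.59e-27). Crabp2, a retinoic acid binding protein, fell from 136 ± 5.31 to 11.2 ± 1.02 CPM (-3.59 ± 0.08, adjusted p = 2.36e-30).

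At day 2, 12359 genes were called, 6187 higher and 6172 lower in the Oct1 cKO, with 1216 higher and 2543 lower by at least 2-fold. With library sizes alone the median of all genes moved by -0.19, and 4263 were called higher and 8187 lower. The genes named in every comparison had 8 higher: Pou5f1, Nanog, Sox2, Zfp42, Gata4, Gata6, Id1 and Cdkn1a. Another 13 were lower: Fgf5, Mixl1, Eomes, Hand1, Kdr, Pax6, Sox1, Foxa2, Rarb, Cyp26a1, Hoxb1, Lefty1 and Col1a1. Tubb3 (-0.30 ± 0.15, adjusted p = 0.0779) and Cdx2 (-0.06 ± 0.42, adjusted p = 0.913) were not called, and Tubb3 had adjusted p from 0.00357 to 0.366 over the alternatives. The call of Nanog (22.9 to 28.8 CPM, 0.32 ± 0.07) was lost with library sizes alone (adjusted p = 0.102, with 1.9e-05 to 0.102 over the alternatives). The largest increases were Mymx (3.90 ± 0.13), Fbp1, Stac3, Ffar3, Platr10, Fgf4, Msln and Fbp2 (16.4 to 140 CPM, 3.10 ± 0.08). The largest decreases besides Meox1 and Kdr were Irgm1 (46.7 to 2.04 CPM, -4.52 ± 0.11), Cyp1b1 (129 to 6.31 CPM, -4.35 ± 0.12), Egr1 (20.9 to 1.04 CPM, -4.31 ± 0.17), Has2, Cdc42ep1 and Jrk.

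Of 26 genes of general and naive pluripotency, 21 were higher and 3 lower at day 2 (camera adjusted p = 0.000174), among them Tdgf1 (110 to 368 CPM, 1.75 ± 0.05) and Fbxo15 (44.8 to 177 CPM, 1.98 ± 0.06). Hox genes of paralogue groups 1 to 5 had 14 of 15 lower and 0 higher (camera adjusted p = 0.00107), and Hoxb3 fell from 49.4 to 7.54 CPM (-2.71 ± 0.09). Without chromosome 11, 9 of these genes were lower. Retinoic acid response genes had 14 of 18 lower and 2 higher (camera adjusted p = 0.000574, adjusted p = 0.112 with an estimated correlation), among them Meis1 (162 to 49.7 CPM, -1.70 ± 0.05) and Cyp26b1 (116 to 29.6 CPM, -1.97 ± 0.06). Imprinted genes had 13 of 20 lower and 4 higher (camera adjusted p = 0.00253), and Mest fell from 1310 to 251 CPM (-2.38 ± 0.05). Proliferation genes had 14 of 19 higher and 3 lower (camera adjusted p = 0.00391, adjusted p = 0.12 with an estimated correlation), such as Ccna2 (251 to 407 CPM, 0.70 ± 0.04). Glycolysis genes had 12 of 17 higher and 1 lower, or 2 lower when adjusted over the list alone (camera adjusted p = 0.0094, adjusted p = 0.476 with an estimated correlation), such as Pfkp (127 to 429 CPM, 1.75 ± 0.05).

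Fibroblast genes had 12 of 18 lower and 2 higher at day 2, or 13 lower when adjusted over the list alone (camera adjusted p = 0.0187, adjusted p = 0.324 with an estimated correlation), and Col1a2 fell from 75.2 to 17.8 CPM (-2.08 ± 0.08). The 2-cell-like list had 11 of 14 higher and 0 lower (camera adjusted p = 0.0283, adjusted p = 0.17 with an estimated correlation). Neural crest genes had 7 of 12 lower and 0 higher (camera adjusted p = 0.0404, adjusted p = 0.113 with an estimated correlation), among them Msx1 (13.7 to 2.58 CPM, -2.41 ± 0.14) and Sox10 (13.5 to 4 CPM, -1.75 ± 0.14). Other replication-dependent histones had 19 of 32 lower and 2 higher (camera adjusted p = 0.048, adjusted p = 0.324 with an estimated correlation). The neural crest call and this one were lost with library sizes alone and without some single libraries, and this one also with the DESeq2 size factors, with adjusted p up to 0.0864 for neural crest and 0.173 for the histones (lowest 0.00819 and 0.0117 over the alternatives). Of 28 primitive streak and early mesoderm genes, 4 were higher and 11 lower, or 3 and 11 when adjusted over the list alone (camera adjusted p = 0.16, not called). Foxc1 fell from 21.6 to 2.76 CPM (-2.96 ± 0.14) and Lhx1 from 6.6 to 0.745 CPM (-3.12 ± 0.24), and 7 members were lower without chromosome 11. Targets of TGF-beta, nodal and BMP signalling had 6 of 23 higher and 12 lower, or 6 and 13 when adjusted over the list alone (camera adjusted p = 0.126, not called). Lefty1 fell from 483 to 95.3 CPM (-2.34 ± 0.06) and Lefty2 from 165 to 73.6 CPM (-1.16 ± 0.06).

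The third comparison asks what differed after 6 days. Pou5f1 was nearly silent in parental cells at 0.362 ± 0.184 CPM and stood at 31 ± 0.598 CPM in the Oct1 cKO (6.4 ± 0.18, adjusted p = 1.94e-22). Kdr fell from 226 ± 15.1 to 12.9 ± 0.372 CPM (-4.13 ± 0.07, adjusted p = 3.76e-35), and Dcx, a microtubule protein of young neurons, from 105 ± 2.48 to 0.769 ± 0.543 CPM (-7.05 ± 0.15, adjusted p = 1.39e-30). Epithelial Cdh1 was higher in the cKO (42.4 ± 3.16 and 517 ± 27.8 CPM, 3.61 ± 0.06, adjusted p = 5.26e-36). Mesenchymal Cdh2 was lower (166 ± 5.55 and 12.1 ± 2.22 CPM, -3.77 ± 0.07, adjusted p = 2.83e-33). From day 0 to day 6, Cdh1 went from 31848 to 2479 counts over 3 libraries in parental cells and from 27688 to 25701 in cKO cells. Cdh2 went from 519 to 9722 counts in parental cells and from 393 to 605 in cKO cells. Both differences thus came mostly with a change in the parental cells.

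At day 6, 13680 genes were called, 6740 higher and 6940 lower in the Oct1 cKO, with 2865 higher and 3734 lower by at least 2-fold. With library sizes alone the median of all genes moved by -0.20, and 5241 were called higher and 8414 lower. Among the genes named in every comparison, 11 were higher: Pou5f1, Sox2, Zfp42, Eomes, Hand1, Tubb3, Gata4, Foxa2, Cdx2, Cyp26a1 and Hoxb1. Another 9 were lower: Nanog, Fgf5, Mixl1, Kdr, Pax6, Gata6, Rarb, Id1 and Col1a1. Lefty1 (-0.26 ± 0.27, adjusted p = 0.383) and Cdkn1a (0.05 ± 0.06, adjusted p = 0.488, with 0.00579 to 1 over the alternatives) were not called, nor was Sox1 at 0.0174 and 0 CPM. The call of Cyp26a1 (275 to 334 CPM, 0.28 ± 0.05) was lost with library sizes alone (adjusted p = 0.166, with 5.69e-08 to 0.166 over the alternatives). Hand1, a mesoderm and trophoblast factor, rose from 17.7 to 93.1 CPM (2.39 ± 0.08) although it lies on chromosome 11, and Gata6 fell from 304 to 68 CPM (-2.16 ± 0.06). Nanog was lower in the cKO at low levels (1.34 and 0.342 CPM, -1.96 ± 0.32, adjusted p = 7.6e-07), and Mixl1 stood at 0.463 and 0.0424 CPM. The higher calls of Sox2 (0.191 and 0.643 CPM) and Hoxb1 (65 and 103 counts over 3 libraries) were also at low levels. The largest increases besides Pou5f1 were Dnmt3l (1.8 to 60.8 CPM, 5.08 ± 0.10), Atp2c2, Chil1, Slc34a2, Zbtb32, Abcc8 and Wfdc2. Besides Dcx the largest decreases were Mybpc1 (23.8 to 0.1 CPM, -7.79 ± 0.24), Gria1 (-7.38 ± 0.22), Pkhd1l1, Ifi203, Iigp1, Vat1l and Tmem255a (222 to 2.06 CPM, -6.74 ± 0.10).

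**Figure D4:**
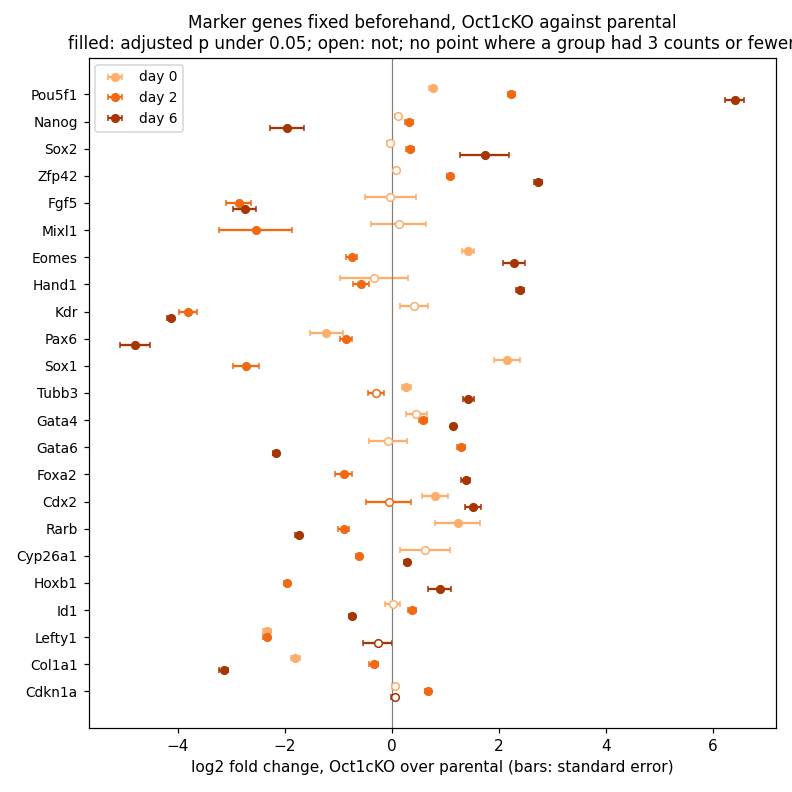
Log2 fold change (± SE) between Oct1 cKO and parental cells at days 0, 2 and 6 for the 23 genes named in every comparison, with a filled point where the adjusted p was under 0.05 and no point where a group held 3 counts or fewer. Pou5f1 moved from 0.76 at day 0 through 2.23 to 6.4, and Kdr from 0.42 through -3.80 to -4.13.

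Pluripotency genes at day 6 had 18 of 26 higher and 3 lower in the general and naive list (camera adjusted p = 0.00102), among them Lin28a (35 to 184 CPM, 2.39 ± 0.05), Sall4 (23.7 to 135 CPM, 2.51 ± 0.05) and Zfp42 (5.92 to 39.4 CPM, 2.73 ± 0.08). The formative and primed list had 4 of 14 higher and 6 lower, or 5 and 6 when adjusted over the list alone, and was not called (camera adjusted p = 0.773). Its members moved apart, with Dnmt3b at 14.2 and 61.7 CPM (2.12 ± 0.07) and Lef1 at 7.99 and 1.02 CPM (-2.95 ± 0.20). The 2-cell-like list had 12 of 14 higher and 1 lower (camera adjusted p = 0.000244), at low levels such as 0.0867 and 4.94 CPM for Zscan4d. Trophoblast genes had 14 of 16 higher and 1 lower (camera adjusted p = 0.000158, adjusted p = 0.0507 with an estimated correlation), among them Tfap2c (38.8 to 246 CPM, 2.67 ± 0.06), Esx1 (4.03 to 48.5 CPM, 3.59 ± 0.09) and Plac1 (33.4 to 142 CPM, 2.08 ± 0.06). The lower member was Tpbpa (98.3 to 36.5 CPM, -1.43 ± 0.07, adjusted p = 1.39e-18). Ctsj (64.5 and 26 CPM) and Ceacam9 (56.7 and 16.6 CPM), placental genes outside the list named here after their values were seen, were also at lower levels in the cKO. Serpinb9e (4129 and 10212 counts over 3 libraries) and Serpinb9b (3243 and 16326), also outside the list, went the other way. Genes picked in this manner give no direction for placental genes as a group. Extraembryonic endoderm genes had 19 of 23 higher and 4 lower (camera adjusted p = 0.00465, adjusted p = 0.13 with an estimated correlation), and Ttr rose from 5.03 to 41.6 CPM (3.05 ± 0.10) while Gata6 fell. Definitive endoderm genes had 7 of 11 higher and 1 lower (camera adjusted p = 0.048, adjusted p = 0.117 with an estimated correlation), and Sox17 rose from 10.5 to 43.8 CPM (2.06 ± 0.09). That call was lost under 6 alternatives, with adjusted p from 0.013 to 0.0697.

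Fibroblast genes had 15 of 18 lower and 1 higher at day 6 (camera adjusted p = 3.94e-05, adjusted p = 0.0939 with an estimated correlation), among them Dcn (113 to 2.84 CPM, -5.30 ± 0.09) and Col6a2 (329 to 12.2 CPM, -4.75 ± 0.08). Hox genes of paralogue groups 1 to 5 had 12 of 15 lower and 3 higher (camera adjusted p = 0.00534, adjusted p = 0.0629 with an estimated correlation), and Hoxc5 fell from 135 to 6.41 CPM (-4.39 ± 0.09). Hox genes of groups 6 to 13 had 14 of 20 lower and 2 higher (camera adjusted p = 0.00668, adjusted p = 0.12 with an estimated correlation), and Hoxc8 fell from 64.4 to 2.63 CPM (-4.61 ± 0.10). Without chromosome 11 the later Hox list lost its call, with 9 members lower (adjusted p = 0.0592, with 0.00244 to 0.0592 over the alternatives). Neuron genes had 10 of 17 lower and 5 higher (camera adjusted p = 0.0283, adjusted p = 0.12 with an estimated correlation), and Nefm fell from 412 to 7.93 CPM (-5.70 ± 0.08) and Stmn2 from 91.3 to 1.88 CPM (-5.59 ± 0.10). Glycolysis genes had 14 of 17 higher and 1 lower (camera adjusted p = 0.00285, adjusted p = 0.424 with an estimated correlation), such as Slc2a3 (275 to 1610 CPM, 2.55 ± 0.05). Other replication-dependent histones had 19 of 32 lower and 1 higher (camera adjusted p = 0.013, adjusted p = 0.231 with an estimated correlation). Library sizes alone ended the calls of the neuron list (adjusted p = 0.0864, with 0.0125 to 0.0864 over the alternatives) and of these histones (adjusted p = 0.0676, with 0.00517 to 0.0676).

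The remaining 14 lists were not called at day 6. Primitive streak and early mesoderm genes had 7 of 28 higher and 13 lower (camera adjusted p = 0.348), with Twist1 lower (45.5 to 3.62 CPM, -3.64 ± 0.11) and Tcf21 lower (54.3 to 5.28 CPM, -3.36 ± 0.10) beside the rise of Hand1. Muscle genes had 8 of 17 higher and 7 lower (camera adjusted p = 0.911), with Myl7 at 6.07 and 34.2 CPM (2.49 ± 0.10) and Mef2c at 7.92 and 0.461 CPM (-4.08 ± 0.24). Endothelium and blood genes had 7 of 11 higher and 1 lower (camera adjusted p = 0.0981, with 0.0118 to 0.195 over the alternatives, 2 of which called it), such as Cdh5 (90.3 to 277 CPM, 1.62 ± 0.06). Neural progenitor genes had 3 of 16 higher and 8 lower (camera adjusted p = 0.164), and neural crest genes 2 of 12 higher and 7 lower (camera adjusted p = 0.433). Retinoic acid response genes had 7 of 18 higher and 11 lower (camera adjusted p = 0.239). Targets of TGF-beta, nodal and BMP signalling had 6 of 23 higher and 13 lower (camera adjusted p = 0.188), with Id3 lower (276 to 31.5 CPM, -3.13 ± 0.07) and Tgfbi lower (530 to 28.5 CPM, -4.21 ± 0.08). Epithelial to mesenchymal genes had 7 of 14 higher and 7 lower (camera adjusted p = 0.858), and those higher included the epithelial genes Cdh1 and Epcam. Other members, Fn1 (64841 and 75035) and Itga5 (14970 and 25536), also had more counts over 3 libraries in the cKO. Proliferation genes had 6 of 19 higher and 8 lower (camera adjusted p = 0.833), p53 target and cell death genes 6 of 15 higher and 5 lower (camera adjusted p = 0.583), and imprinted genes 10 of 20 higher and 8 lower (camera adjusted p = 0.872). X inactivation and Y chromosome genes had 4 of 5 higher and 1 lower (camera adjusted p = 0.194). Replication-dependent H2B histones had 0 of 11 higher and 8 lower (camera adjusted p = 0.0546), and 6 alternatives called that list, with adjusted p from 0.0287 to 0.129.

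**Figure D5:**
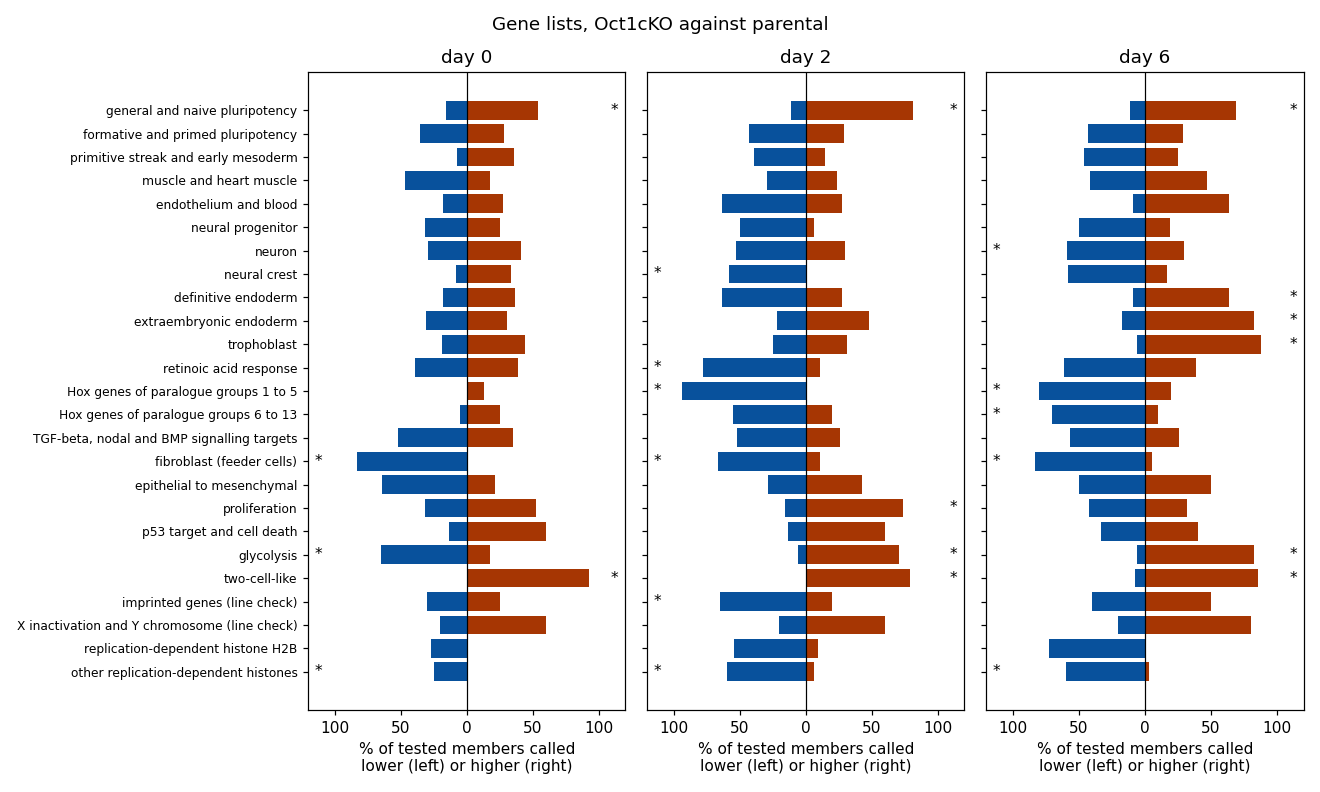
Percent of the tested members of each of the 25 lists called lower (left) or higher (right) in Oct1 cKO than in parental cells at days 0, 2 and 6, with an asterisk on the side of a camera call. At day 6, 14 of 16 trophoblast genes were higher and 15 of 18 fibroblast genes lower.

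In parental cells, Hoxb1 and Cyp26a1 were switched on and pluripotency genes fell by day 2 of differentiation with retinoic acid. No group was kept to day 2 or day 6 without retinoic acid, so its effect cannot be separated from time or other changes of the culture. Hoxb1 rose from 0 counts to 346 CPM, at least 1910-fold, and Cyp26a1, which degrades retinoic acid, rose from 0.258 to 338 CPM (10.30 ± 0.12, adjusted p = 1.01e-40). Nanog fell from 990 to 22.9 CPM (-5.43 ± 0.07, adjusted p = 6.97e-40) and Pou5f1 from 893 to 93.2 CPM (-3.26 ± 0.07, adjusted p = 3.45e-25). Single genes of early mesoderm that rose were Meox1 (0.0832 to 19.6 CPM, 7.81 ± 0.30), Kdr (1.1 to 10.2 CPM, 3.21 ± 0.16) and Foxc1 (0.915 to 21.6 CPM, 4.54 ± 0.17). Lefty1 rose from 107 to 483 CPM (2.17 ± 0.05).

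At day 2, 14837 genes were called against day 0 in parental cells, 7924 higher and 6913 lower. Library sizes alone moved the median of all genes by 0.34 and gave 10130 higher and 4589 lower. Among the 23 genes named throughout, 14 were higher: Fgf5, Eomes, Hand1, Kdr, Pax6, Sox1, Gata4, Gata6, Foxa2, Rarb, Cyp26a1, Hoxb1, Id1 and Lefty1. Those lower were 8: Pou5f1, Nanog, Sox2, Zfp42, Tubb3, Cdx2, Col1a1 and Cdkn1a. Mixl1 was not called (0.25 ± 0.46, adjusted p = 0.622). Large increases included Arg1 (0.0603 to 72 CPM), Hoxb3os, Grifin, Hoxb5 and Cubn, and Csn3 stood at 0.0208 and 78.8 CPM. Large decreases included Foxd3 (56.8 to 0.319 CPM, -7.43 ± 0.15), Prdm14, Trpm1, Nr5a2, Tcl1, Mep1b and Osm, and Spic stood at 50.8 and 0.0166 CPM.

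Lists called higher at day 2 in parental cells were Hox genes of groups 1 to 5 (15 of 15 higher, camera adjusted p = 4.75e-07), 2-cell-like (14 of 14 higher, camera adjusted p = 7.2e-05) and imprinted genes (15 of 20 higher and 5 lower, camera adjusted p = 0.00212). Retinoic acid response genes had 15 of 18 higher and 2 lower (camera adjusted p = 6.92e-06, adjusted p = 0.0507 with an estimated correlation), Hox genes of groups 6 to 13 had 18 of 20 higher and 2 lower (camera adjusted p = 0.000255, adjusted p = 0.0507 with an estimated correlation), and extraembryonic endoderm genes had 17 of 23 higher and 3 lower (camera adjusted p = 0.000832, adjusted p = 0.0795 with an estimated correlation). Primitive streak and early mesoderm genes had 23 of 28 higher and 3 lower (camera adjusted p = 0.00228, adjusted p = 0.0659 with an estimated correlation). Weaker calls were those of other replication-dependent histones (26 of 32 higher, camera adjusted p = 0.0157, adjusted p = 0.241 with an estimated correlation), definitive endoderm (8 of 11 higher and 2 lower, camera adjusted p = 0.0362, adjusted p = 0.104 with an estimated correlation) and neural crest (8 of 12 higher and 1 lower, camera adjusted p = 0.0485, adjusted p = 0.12 with an estimated correlation). Library sizes alone ended these 3 calls, with adjusted p up to 0.0827, 0.0868 and 0.139 over the alternatives and from 0.00683, 0.0227 and 0.0121. Called lower were general and naive pluripotency (23 of 26 lower and 2 higher, camera adjusted p = 4.07e-08), proliferation (14 of 19 lower and 2 higher, camera adjusted p = 0.000841, adjusted p = 0.0783 with an estimated correlation) and fibroblast genes (13 of 18 lower and 2 higher, camera adjusted p = 0.00138, adjusted p = 0.191 with an estimated correlation). Targets of TGF-beta, nodal and BMP signalling had 8 of 23 higher and 14 lower and were not called (camera adjusted p = 0.467).

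By day 6 every tested gene of the general and naive pluripotency list was lower in parental cells, and genes of extraembryonic endoderm were higher. Gdf3 fell from 144 CPM to 0 counts, at least 934-fold, and Pou5f1 from 893 to 0.362 CPM (-11.25 ± 0.14, adjusted p = 9.9e-32). Kdr rose to 226 CPM (7.67 ± 0.10, adjusted p = 2.76e-39), Gata6 from 0.705 to 304 CPM (8.74 ± 0.11, adjusted p = 1.44e-40) and Col4a1, a basement membrane collagen, from 156 to 4450 CPM (4.84 ± 0.05). Tpbpa, a trophoblast gene, rose from 0 counts to 98.3 CPM, at least 544-fold, and Tcf21 from 0 counts to 54.3 CPM, at least 301-fold. H19, an imprinted RNA, rose from 71 to 11200 CPM (7.30 ± 0.07), which was 1.12 to 1.191% of all counts in those libraries.

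Against day 0, 15688 genes were called at day 6 in parental cells, 8315 higher and 7373 lower. Higher were 13 of the 23 genes: Fgf5, Hand1, Kdr, Pax6, Gata4, Gata6, Foxa2, Cdx2, Rarb, Cyp26a1, Hoxb1, Id1 and Col1a1. Lower were 9: Pou5f1, Nanog, Sox2, Zfp42, Eomes, Sox1, Tubb3, Lefty1 and Cdkn1a, and Mixl1 was not called (-0.22 ± 0.50, adjusted p = 0.68). Other genes that rose from 0 counts were Serpinb9e, at least 391-fold, Ctsj, at least 357-fold, Ceacam9, at least 314-fold, and Tgm5, at least 313-fold, and Spic fell to 0 counts, at least 330-fold. Levels at day 0 and day 6 were 0.0207 and 222 CPM for Tmem255a, 0.0415 and 259 for Gucy1a1, 446 and 0.0519 for Fgf4, 132 and 0.0166 for Mep1b, 87.4 and 0.0173 for Tcl1, 77.7 and 0.0173 for Dppa3 and 154 and 0.0513 for Ooep.

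Pluripotency was the list with the smallest camera adjusted p at day 6 in parental cells (2.31e-12), with 26 of 26 lower. Proliferation genes had 17 of 19 lower and 0 higher (camera adjusted p = 9.14e-06). Extraembryonic endoderm genes had 22 of 23 higher and 1 lower (camera adjusted p = 1.13e-07), Hox genes of groups 1 to 5 had 14 of 15 higher (camera adjusted p = 7.65e-05), and imprinted genes had 15 of 20 higher and 4 lower (camera adjusted p = 0.00182). Calls lost with an estimated correlation were retinoic acid response (14 of 18 higher and 3 lower, camera adjusted p = 0.00102, adjusted p = 0.123 with an estimated correlation), fibroblast (15 of 18 higher and 3 lower, camera adjusted p = 0.0157, adjusted p = 0.316 with an estimated correlation), trophoblast (12 of 16 higher and 4 lower, camera adjusted p = 0.0303, adjusted p = 0.229 with an estimated correlation) and Hox genes of groups 6 to 13 (15 of 20 higher and 4 lower, or 5 lower when adjusted over the list alone, camera adjusted p = 0.0307, adjusted p = 0.223 with an estimated correlation). The 2-cell-like list had 12 of 14 lower and 1 higher (camera adjusted p = 0.00131, adjusted p = 0.0573 with an estimated correlation) and glycolysis 13 of 17 lower and 3 higher (camera adjusted p = 0.0078, adjusted p = 0.468 with an estimated correlation). Library sizes alone or leaving out chromosome 11 ended the trophoblast call (0.0125 to 0.0771 over the alternatives) and that of the later Hox genes (0.0125 to 0.1). Early mesoderm genes had 16 of 28 higher and 7 lower (camera adjusted p = 0.141) and targets of TGF-beta, nodal and BMP signalling 12 of 23 higher and 9 lower (camera adjusted p = 0.839), neither called. Lefty2 fell from 281 to 0.242 CPM (-10.15 ± 0.12) and Nodal from 147 to 0.291 CPM (-8.95 ± 0.14), and Id1 rose from 5.31 to 84.9 CPM (4 ± 0.09).

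Oct1 cKO cells also lowered pluripotency genes and switched on Cyp26a1 by day 2, and Kdr moved the other way from the parental course. Kdr fell from 1.51 to 0.723 CPM (-1.01 ± 0.29, adjusted p = 0.00196). Hoxb1 stood at 0.0251 and 88.7 CPM, and Cyp26a1 rose from 0.407 to 220 CPM (9.06 ± 0.12, adjusted p = 8.09e-39). Nanog fell from 1070 to 28.8 CPM (-5.21 ± 0.07, adjusted p = 4.45e-39) and Pou5f1 from 1520 to 439 CPM (-1.79 ± 0.07, adjusted p = 8.48e-20). Tdh, a threonine catabolic enzyme of ESCs, fell from 626 to 5.07 CPM (-6.95 ± 0.07, adjusted p = 8.96e-42).

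In the cKO, 14039 genes were called at day 2 against day 0, 7525 higher and 6514 lower, and 8543 and 5511 with library sizes alone. Higher were 10 of the 23 genes: Hand1, Pax6, Gata4, Gata6, Foxa2, Rarb, Cyp26a1, Hoxb1, Id1 and Lefty1. Lower were 12: Pou5f1, Nanog, Sox2, Zfp42, Mixl1, Eomes, Kdr, Sox1, Tubb3, Cdx2, Col1a1 and Cdkn1a. Fgf5 was not called (0.75 ± 0.43, adjusted p = 0.127). Large increases included Hoxb3os, Cubn, Car4 (0.699 to 215 CPM, 8.27 ± 0.11), Timd2, Mmp9 and Hoxb5, and large decreases Spic, Trpm1, Foxd3, Zfp819, Serpinb9b, Cdhr1 and Aoah. Foxa2 stood at 0.0251 and 2.37 CPM. Lists that held with an estimated correlation were pluripotency (24 of 26 lower and 1 higher, camera adjusted p = 7.49e-08), Hox genes of groups 1 to 5 (15 of 15 higher, camera adjusted p = 6.92e-06) and imprinted genes (16 of 20 higher and 4 lower, camera adjusted p = 0.00573). Retinoic acid response genes had 15 of 18 higher and 2 lower (camera adjusted p = 7.88e-05, adjusted p = 0.076 with an estimated correlation), extraembryonic endoderm 17 of 23 higher and 3 lower (camera adjusted p = 0.00101, adjusted p = 0.0867 with an estimated correlation) and 2-cell-like 14 of 14 higher (camera adjusted p = 0.003, adjusted p = 0.0766 with an estimated correlation). Hox genes of groups 6 to 13 had 16 of 20 higher and 2 lower (camera adjusted p = 0.00344, adjusted p = 0.103 with an estimated correlation) and other replication-dependent histones 18 of 32 higher, or 16 when adjusted over the list alone (camera adjusted p = 0.0294, adjusted p = 0.286 with an estimated correlation). Without chromosome 11 the later Hox call was lost (adjusted p = 0.06, with 0.001 to 0.06 over the alternatives), and with library sizes alone that of the histones (adjusted p = 0.0704, with 0.00391 to 0.0704). Fibroblast genes had 15 of 18 lower and 2 higher (camera adjusted p = 0.00465, adjusted p = 0.241 with an estimated correlation). Early mesoderm genes had 14 of 28 higher and 8 lower (camera adjusted p = 0.438) and targets of TGF-beta, nodal and BMP signalling 10 of 23 higher and 12 lower (camera adjusted p = 0.745), neither called.

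By day 6 genes of extraembryonic endoderm and trophoblast had risen in the Oct1 cKO cells. Cdh5, the cadherin of endothelium, rose from 0.109 to 277 CPM (11.10 ± 0.14, adjusted p = 8e-40) and Col4a1 from 137 to 9470 CPM (6.12 ± 0.06, adjusted p = 1.29e-43). Apoa1 and Ttr, secreted by visceral endoderm, rose from 0 counts to 44 CPM, at least 203-fold, and to 41.6 CPM, at least 192-fold. Hand1 rose from 0.231 to 93.1 CPM (8.57 ± 0.18), and Nanog fell from 1070 to 0.342 CPM (-11.58 ± 0.11, adjusted p = 2.18e-43). Krt7, a simple epithelial keratin, rose from 2.51 to 379 CPM (7.23 ± 0.09).

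At day 6, 15009 genes were called against day 0 in the cKO, 7592 higher and 7417 lower. Higher were 12 of the 23 genes: Fgf5, Hand1, Kdr, Gata4, Gata6, Foxa2, Cdx2, Rarb, Cyp26a1, Hoxb1, Id1 and Col1a1. Lower were the other 11: Pou5f1, Nanog, Sox2, Zfp42, Mixl1, Eomes, Pax6, Sox1, Tubb3, Lefty1 and Cdkn1a. The libraries of day 0 and day 6 overlapped for Fgf5 alone, and its call (0.327 to 0.691 CPM, 1.02 ± 0.41, adjusted p = 0.0236) was lost under DESeq2 and without any of 3 single libraries (0.00923 to 0.175 over the alternatives). Nos2 rose from 0 counts at least 192-fold and Tpbpa at least 169-fold. Falls to 0 counts were at least 335-fold for Pla2g1b, 322-fold for Foxd3, 277-fold for Pipox, 206-fold for Aoah, 165-fold for Olig2 and 21.7-fold for Sox1. Levels at day 0 and day 6 were 0.0261 and 45.2 CPM for Habp2, 0.0251 and 35.2 for Foxa2, 133 and 0.0193 for Platr10, 181 and 0.0392 for Mcf2 and 0.574 and 0.0424 for Mixl1. Serpinb9e and Fgf4 completed the largest changes (10.41 ± 0.16 and -11.24 ± 0.13). Lists that held with an estimated correlation were pluripotency (25 of 26 lower and 1 higher, camera adjusted p = 5.6e-10), extraembryonic endoderm (22 of 23 higher, camera adjusted p = 1.22e-08), trophoblast (15 of 16 higher and 1 lower, camera adjusted p = 6.55e-06), proliferation (18 of 19 lower and 1 higher, camera adjusted p = 1.43e-05), imprinted genes (17 of 20 higher and 3 lower, camera adjusted p = 0.000158) and Hox genes of groups 1 to 5 (13 of 15 higher, camera adjusted p = 0.00109). The 2-cell-like list had 13 of 14 lower (camera adjusted p = 0.000841, adjusted p = 0.0507 with an estimated correlation) and retinoic acid response 14 of 18 higher and 3 lower (camera adjusted p = 0.00112, adjusted p = 0.128 with an estimated correlation). Early mesoderm genes had 12 of 28 higher and 12 lower (camera adjusted p = 0.7) and targets of TGF-beta, nodal and BMP signalling 10 of 23 higher and 9 lower (camera adjusted p = 0.98), neither called.

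The interaction tests ask whether the change from day 0 differed between the genotypes. From day 0 to day 2, Kdr rose in parental cells and fell in the Oct1 cKO, a difference of -4.22 ± 0.35 on the log2 scale (adjusted p = 3.51e-13), and Eomes did the same (5.4 to 15.3 and 14.4 to 9.13 CPM, -2.16 ± 0.15, adjusted p = 4.14e-15). Irgm1, an interferon-induced GTPase, went from 6.77 to 46.7 CPM in parental and from 11.8 to 2.04 CPM in cKO cells (-5.33 ± 0.16, adjusted p = 2.67e-25). Rarb, a retinoic acid receptor and target, rose less in the cKO (-2.13 ± 0.43, adjusted p = 5.76e-05). Pou5f1 fell less in the cKO at day 2 (1.47 ± 0.09, adjusted p = 1.3e-13) and at day 6 (5.64 ± 0.21, adjusted p = 5.79e-19). From day 0 to day 6, Nefm, a neurofilament gene, rose in parental cells (24.8 to 412 CPM) and fell in the cKO (60.6 to 7.93 CPM), a difference of -6.99 ± 0.11 (adjusted p = 7.88e-34). Hand1 rose more in the cKO (2.72 ± 0.66, adjusted p = 0.00046).

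The day 2 interaction was called for 10463 genes, 5526 positive and 4937 negative, and 4094 and 6317 with library sizes alone. Not called were Hand1 (-0.24 ± 0.70), Pax6 (0.36 ± 0.33), Gata4 (0.12 ± 0.22), Foxa2, Cdx2, Hoxb1 and Lefty1 (-0.01 ± 0.09, adjusted p = 0.953). Lists called at day 2 were pluripotency (20 of 26 positive and 4 negative, camera adjusted p = 0.00538, adjusted p = 0.0585 with an estimated correlation), early mesoderm (16 of 28 negative and 2 positive, camera adjusted p = 0.0104, adjusted p = 0.112 with an estimated correlation), neural crest (6 of 12 negative, camera adjusted p = 0.0078, adjusted p = 0.0551 with an estimated correlation) and retinoic acid response (13 of 18 negative and 4 positive, camera adjusted p = 0.00212, adjusted p = 0.152 with an estimated correlation). Hox genes of groups 1 to 5 had 8 of 15 negative, or 7 when adjusted over the list alone (camera adjusted p = 0.00109), and were the one list whose interaction call held with an estimated correlation (adjusted p = 0.0387). Hox genes of groups 6 to 13 had 8 of 20 negative (camera adjusted p = 0.0283, adjusted p = 0.212 with an estimated correlation), proliferation 12 of 19 positive and 3 negative, or 4 negative when adjusted over the list alone (camera adjusted p = 0.0255, adjusted p = 0.229 with an estimated correlation) and glycolysis 14 of 17 positive and 1 negative (camera adjusted p = 0.000244, adjusted p = 0.316 with an estimated correlation). The 2-cell-like list had 13 of 14 negative (camera adjusted p = 0.000889, adjusted p = 0.0507 with an estimated correlation) and imprinted genes 11 of 20 negative and 5 positive (camera adjusted p = 0.0148, adjusted p = 0.0573 with an estimated correlation). Library sizes alone or leaving out chromosome 11 ended the calls of the later Hox genes (0.0135 to 0.0717 over the alternatives) and proliferation (0.0152 to 0.121). Targets of TGF-beta, nodal and BMP signalling were not called (camera adjusted p = 0.84).

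The day 6 interaction was called for 11730 genes, 5873 positive and 5857 negative, and 4801 and 7145 with library sizes alone. Not called were Sox1, Cyp26a1 (-0.34 ± 0.46), Hoxb1 and Cdkn1a (-0.01 ± 0.09). Lists called were pluripotency (16 of 26 positive and 3 negative, or 17 positive when adjusted over the list alone, camera adjusted p = 0.00331, adjusted p = 0.0507 with an estimated correlation), trophoblast (12 of 16 positive, camera adjusted p = 0.00212, adjusted p = 0.0939 with an estimated correlation), extraembryonic endoderm (11 of 23 positive and 3 negative, camera adjusted p = 0.0288, adjusted p = 0.241 with an estimated correlation) and glycolysis (13 of 17 positive, camera adjusted p = 0.00016, adjusted p = 0.296 with an estimated correlation). Negative were neuron (10 of 17 negative and 2 positive, or 3 positive when adjusted over the list alone, camera adjusted p = 0.0205, adjusted p = 0.108 with an estimated correlation), Hox genes of groups 1 to 5 (10 of 15 negative, camera adjusted p = 0.00285, adjusted p = 0.0507 with an estimated correlation), Hox genes of groups 6 to 13 (14 of 20 negative, camera adjusted p = 0.000529, adjusted p = 0.0573 with an estimated correlation) and fibroblast genes (12 of 18 negative and 2 positive, or 13 negative when adjusted over the list alone, camera adjusted p = 0.003, adjusted p = 0.229 with an estimated correlation). Library sizes alone ended the neuron call (0.01 to 0.0587 over the alternatives), and leaving out chromosome 11 or replicate 3 of the cKO at day 0 ended that of extraembryonic endoderm (0.0131 to 0.064).

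Across the 225 list tests, camera called 85, and 25 of these held with an estimated correlation. Those 25 were the general and naive pluripotency list at days 2 and 6 between genotypes and in all 4 courses, Hox genes of groups 1 to 5 in 6 tests, imprinted genes in 5, 2-cell-like in 3, extraembryonic endoderm in 2, proliferation in 2 and trophoblast in 1. The median, the mean and the test of a list differed in sign in 27 tests, and 0 of those 27 was called. They were neural progenitor, neuron, extraembryonic endoderm and retinoic acid response between genotypes at day 0, formative, extraembryonic endoderm and epithelial to mesenchymal at day 2, and formative and epithelial to mesenchymal at day 6. In parental cells they were formative, neuron and X inactivation and Y chromosome at day 2, and neural progenitor, definitive endoderm, TGF-beta and epithelial to mesenchymal at day 6. In cKO cells they were formative, muscle, endothelium and neuron at day 2, and endothelium, later Hox, TGF-beta and epithelial to mesenchymal at day 6. The interactions had other histones at day 2 and p53 and imprinted at day 6.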

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

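In this part, the tests of copy number on chromosome 11 and of feeder fibroblasts were chosen after the results were seen. So was that of day 0 cells left at day 6. For GC content and gene length, and for day 2 cells left at day 6, the expectations were written before those tests were run. Both of these tests still address a pattern that had already been seen, and the day 2 test has the same bounds as the day 0 test. The genes and lists of the next 2 paragraphs were picked out because the change from day 0 differed between parental and Oct1 cKO cells in an interaction test, and positive values mean a higher change in the cKO.

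For day 2 the test called 10463 genes. Among the largest positive differences were those in Iqca (4.66), Rph3al (4.19), Nupr1 (3.81) and Ubap1l (3.66), and the largest negative ones in Irgm1 (-5.33), Jrk (-4.88), Sox1 (-4.87), Apob (-4.73) and Egr1 (-4.56). Nupr1, a stress-response gene, fell from 16.5 to 11.3 CPM in parental cells and rose from 6.65 to 64.9 CPM in the cKO. Pluripotency genes fell less in the cKO: Pou5f1 (1.47), Sox2 (0.39) and Zfp42 (1.02), and Nanog (0.21) with a call lost under 13 of 18 alternatives. Lineage and signalling genes with a lower change were Fgf5 (-2.82), Mixl1 (-2.68), Eomes (-2.16), Kdr (-4.22), Tubb3 (-0.58), Rarb (-2.13) and Cyp26a1 (-1.24). Those with a higher change were Gata6 (1.37), Id1 (0.37), Col1a1 (1.47) and Cdkn1a (0.61). Col1a1 fell in both genotypes and stayed lower in the cKO, with 26991 and 3516 counts over 3 libraries in parental and 6499 and 2150 in cKO cells. Nanog had adjusted p = 0.0358 (0.00567 to 0.76 over the alternatives). The call of Id1 was lost under 16 of 18 alternatives (adjusted p = 0.0452, with 0.0128 to 0.317) and that of Cyp26a1 under 5 (adjusted p = 0.0336, with 0.0146 to 0.0971). Camera adjusted p for the lists was 0.00538 for pluripotency (positive), 0.0104 for early mesoderm, 0.0078 for neural crest, 0.00212 for retinoic acid response, 0.00109 for Hox genes of groups 1 to 5, 0.0283 for groups 6 to 13, 0.000889 for 2-cell-like and 0.0148 for imprinted genes (all negative), 0.0255 for proliferation and 0.000244 for glycolysis (both positive). With an estimated correlation the Hox list of groups 1 to 5 held (adjusted p = 0.0387) and the other 9 lay between 0.0507 and 0.316.

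For day 6 the test called 11730 genes. The largest positive differences were in Dmrtc1b (6.73), Abcc8 (5.98) and Pou5f1 (5.64), with Nos2 (adjusted p = 2.41e-06) and Pramel7 (adjusted p = 4.31e-05), which had 0 counts in a group. The largest negative ones were in Mybpc1 (-7.63), Nefm (-6.99), Ngfr (-6.75) and Ildr2 (-6.54), with Gucy1a1 (adjusted p = 0.000154), which had few counts at day 0. Ngfr, a neurotrophin receptor of neural crest, held 23.4 and 24.9 CPM at days 0 and 6 in parental cells and fell from 59.6 to 0.583 CPM in the cKO. A higher change in the cKO was called for Sox2 (1.78), Zfp42 (2.67), Eomes (0.86), Hand1 (2.72), Tubb3 (1.15), Gata4 (0.68), Cdx2 (0.70), Lefty1 (2.07) and Foxa2 (adjusted p = 0.000664). Lefty1 fell in both genotypes, from 5351 to 65 counts over 3 libraries in parental and from 894 to 46 in cKO cells. It was not called between genotypes at day 6. A lower change was called for Nanog (-2.07), Fgf5 (-2.72), Kdr (-4.55), Pax6 (-3.58), Gata6 (-2.09), Rarb (-2.97), Id1 (-0.76), Col1a1 (-1.33) and Mixl1 (adjusted p = 0.00491). The call of Cdx2 was lost under 9 of 18 alternatives (adjusted p = 0.0348, with 0.00457 to 0.133). Camera adjusted p for the lists was 0.00331 for pluripotency, 0.0288 for extraembryonic endoderm, 0.00212 for trophoblast and 0.00016 for glycolysis (positive), and 0.0205 for neuron, 0.00285 for Hox genes of groups 1 to 5, 0.000529 for groups 6 to 13 and 0.003 for fibroblast genes (negative). With an estimated correlation these 8 lay between 0.0507 and 0.296.

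The genes of chromosome 11 were lower in the Oct1 cKO at all 3 days. Fewer copies of the chromosome in the cKO cells would lower every part of it at every day, and the highest median of its 20-Mb bins over the days was -0.35 relative to the other autosomes, so the pattern is consistent with that explanation. GC content and gene length were excluded, since the median after their correction was at most -0.46. Single 20-Mb bins of the other autosomes reached -0.43 at day 0, -0.22 at day 2 and -0.60 at day 6. Loss of 1 of 3 copies would give -0.58 on the log2 scale, but the number of copies in the parental line is not known. The median of the whole chromosome relative to the other autosomes was -0.4 at day 0, -0.47 at day 2 and -0.49 at day 6, short of that value. DNA was not analysed here, and genotype cannot be separated from line.

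Pou5f1 stayed at 31 CPM in the cKO at day 6. If cells left at their day 0 state explained this, they would supply 2.02% of the sequenced RNA. That is also their share of the cells only if RNA per cell was alike, which was not measured. The 54 marker genes held at least 50 CPM in the cKO at day 0 and at most 1% of that level in parental cells at day 6. Of these, 57.4% (31) lay below 0.5 of the level that share brings, so cells left unchanged from day 0 do not alone explain it. For day 0 cells, Nanog at 0.342 CPM against 21.5 needed, Sox2 at 0.643 against 8.93 and Fgf4 at 0.141 against 7.22 lay below. Other markers reached the needed level: Utf1 at 18.7 CPM against 2.55, Tfcp2l1 at 63.8 against 26.5, Dppa5a at 61.1 against 52.9 and Dppa4 at 3.35 against 2.64. Cells left unchanged from day 2, at a share of 6.98% of the sequenced RNA, do not alone explain it either. Of 33 marker genes for them, 63.6% (21) lay below 0.5 of the level that share brings. Cells left in a partly changed state and a change of regulation in the cells themselves were not tested.

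Fibroblast genes were lower in the cKO at day 0 and at day 6. At day 0, fewer feeder fibroblasts would lower all members alike, and the log2 fold changes of the 12 members with at least 10 CPM had an SD of 0.37, from -1.82 to -0.72, which cannot tell that explanation from regulation in the ESCs. At day 6, the test of feeder cells carried over from day 0 asked whether the members changed alike in parental cells. They did not, so a change in feeder number alone does not account for the parental levels at day 6. The test used no cKO value, so it cannot say what feeder cells add to the difference between genotypes. The parental log2 change of the 14 members with at least 10 CPM from day 0 to day 6 spanned 9.90, from -3.89 for Thy1 to 6.01 for Dcn. The labels do not say whether feeder cells were used.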

How the results depend on the processing

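Of the 9 counts of called genes, all stayed within 1.5 times the reported count under the DESeq2 size factors, library sizes alone, no filter, DESeq2, only the libraries compared and chromosome 11 left out. Leaving out single libraries gave 8979 to 9444 genes between genotypes at day 0, 11721 to 11935 at day 2 and 13301 to 13408 at day 6. A fold minimum of 2 left 2333, 3759 and 6599 genes at days 0, 2 and 6 between genotypes, 7308 and 9527 at days 2 and 6 in parental cells, 7295 and 9309 in cKO cells, and 4208 and 6303 for the interactions, since it asks for larger changes. A test against a fold of 1.5, chosen after seeing the data, left 2339, 4531 and 7804 between genotypes, 8885 at day 2 in parental and 8801 in cKO cells, and 4539 and 7086 for the interactions. Camera called 85 list tests, 83 to 88 without single libraries, 84 with the DESeq2 size factors, 74 with library sizes alone, 91 with no filter and 79 without chromosome 11. An estimated correlation called 25, and fry, which does not compare a list with other genes, called 198.

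Genes whose direction turned were not called in the main fit, apart from Pou2f1 at day 2 in parental cells (adjusted p = 0.00538). The cause was not tested. With library sizes alone, Cdkn1a between genotypes at day 6 stood at -0.16 and was called lower (adjusted p = 0.0198). The log2 value there was 0.02 for Pou2f1 at day 2 in parental cells, -0.06 for Gata4 in the day 2 interaction and -0.09 for Pou2f1 in the day 6 interaction. Cdkn1a in the day 6 interaction was 0.02 with the DESeq2 size factors, no filter or DESeq2. Without single libraries, day 0 values between genotypes ran from -0.33 to 0.29 for Fgf5, -0.35 to 0.66 for Mixl1, -0.85 to 0.19 for Hand1, -0.60 to 0.13 for Gata6, 0 to 2.66 for Hoxb1 and -0.12 to 0.10 for Id1. Later they ran from -0.24 to 0.16 for Cdx2 at day 2, and from -2.14 to 0 for Sox1 and -0.01 to 0.19 for Cdkn1a at day 6. The values of Hoxb1 (1 count at day 0 over both genotypes) and Sox1 (1 count at day 6) rest on single reads and give no size of change. In parental cells Mixl1 ran from -0.05 to 0.78 at day 2 and from -0.57 to 0.31 at day 6. Day 2 interactions ran from -0.24 to 0 for Pou2f1, -0.76 to 0.27 for Hand1 and -0.09 to 0.08 for Lefty1, and those of day 6 from -0.07 to 0.19 for Pou2f1, -1.79 to 0.89 for Hoxb1 (the same single read) and -0.10 to 0.10 for Cdkn1a.

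Lists that turned direction were not called by camera. Fry gave adjusted p = 6.59e-06 for formative pluripotency, 0.258 for muscle and 1.28e-05 for imprinted genes between genotypes at day 6, and for targets of TGF-beta, nodal and BMP signalling 0.0423 at day 2 in parental and 0.198 in cKO cells. Without chromosome 11 it was 0.633 for muscle, 0.881 for epithelial to mesenchymal and 0.952 for proliferation between genotypes at day 6, and 0.958 for the TGF-beta targets at day 6 in parental cells. Without single libraries the TGF-beta targets ran from 0.902 to 0.994 at day 6 in cKO cells and from 0.81 to 0.97 in the day 2 interaction. Leaving out chromosome 11 was chosen after seeing the data.

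Depth limits the genes with few counts: Mixl1, Sox1 and Fgf5 lay below 6 CPM in every group. No paired analysis was possible because the replicate numbers follow the order of the samples and the labels do not say which libraries share a culture.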

Other observations

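The descriptions of POU genes and of the overlap between days were chosen after results had been seen, and the Y genes and the tests of the slope and of other splits before theirs. Some other POU genes differed between the genotypes. Of the 11 tested POU genes besides Pou2f1, 5 were higher and 1 lower in the Oct1 cKO at day 0, 5 and 4 at day 2, and 2 and 4 at day 6, where 53.5%, 67.3% and 74.5% of all genes were called. Pou2f3, the paralogue of Pou2f1 known from chemosensory epithelial cells, was higher at every day: 8.56 and 89.4 CPM at day 0, 0.931 and 4.32 at day 2 (log2 fold change 2.21, adjusted p = 9.62e-13), and 1.76 and 8.29 at day 6 (2.23, adjusted p = 1.09e-16). Pou2f2, which encodes Oct2, was lower at day 0 (5.47 and 2.22 CPM, -1.30, adjusted p = 9.17e-08) and not called at day 2 (0.01, adjusted p = 0.958) or day 6 (-0.50, adjusted p = 0.241). Pou3f1, a factor of the epiblast and early neural tissue, was higher at day 0 (0.37, adjusted p = 0.0461) and lower at day 2 (-0.70, adjusted p = 1.58e-08) and day 6 (-1.54, adjusted p = 2.33e-13). Pou6f1 was lower at day 6 (15.2 and 2.66 CPM, -2.51, adjusted p = 9.83e-20).

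The lines differed in genes of the Y chromosome. Kdm5d, a histone demethylase gene, was lower in the cKO at days 0, 2 and 6 (29.1 and 7.25, 29.1 and 13.6, 44.1 and 15.5 CPM). Ddx3y was higher (137 and 265, 104 and 264, 116 and 332 CPM), as were Uty (39.1 and 72.3, 38.3 and 107, 48.1 and 87.4 CPM) and Eif2s3y (130 and 177, 84.6 and 213, 73.8 and 189 CPM). Both lines therefore express Y genes. Xist stood at 1.74 and 3.09, 5.81 and 7.55, and 9.1 and 20.4 CPM. Imprinted genes moved apart at day 6: Peg10 was higher in the cKO (3000 and 14500 CPM) and Mest lower (1820 and 206 CPM).

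Genes different between genotypes at day 2 were also different at day 6 more than by chance: among those lower by at least 2-fold, 1260 were shared against 517 by chance, and 449 against 190 among those higher. Days 0 and 2 shared 298 lower genes against 167 and 216 higher against 75. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.35 between days 2 and 6, 0.12 between days 0 and 6 and 0.11 between days 0 and 2.

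A hypothesis written before its test was run was that the cKO cells follow the parental course with smaller steps. Across the 14837 genes called in the parental course at day 2, the slope of the cKO change on the parental change was 0.88 (0.86 to 0.90 without single libraries), which did not clear the bound set for it, so the test cannot tell. At day 6, over 15688 genes, the slope was 0.87 (0.86 to 0.88) and cleared it. The same direction was seen for 82% and 80.3% of the genes, and 57.6% and 56.7% changed less in the cKO. Choosing genes by the parental change favours smaller changes in the other line, so the slopes may in part come from that choice.

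Genes were also counted after dividing the libraries in other ways, with only the compared libraries refitted. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In each of these 7 comparisons 1 split, the real one, called the most genes. The real splits called 8750, 12131 and 13148 genes between genotypes at days 0, 2 and 6, 14371 and 15023 in the parental course and 12646 and 13518 in the cKO course, and the highest other split called 0 in each. Every other split mixed both real groups on each side, so the difference between them entered its spread and left little to call. These counts are therefore no support for the calls. For the interactions 40 splits were drawn, the real one included, and they also mixed days and genotypes, so they do not test the interaction alone and the question is left open. The real ones called 10106 at day 2, against 4297 at most, and 11515 at day 6, against 5528.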
